A study of Homo sapiens with 54 samples.

How the data were processed

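RNA from HT-29 cells was hybridized to Affymetrix human genome arrays. Per the labels' protocols the cells were seeded at 50000 cells per cm2 and given 200 U/ml interferon-gamma for 24 h before the treatments, and the series describes biological duplicates. The deposited values are linear MAS5 signals, and their unit was taken as intensity. Per the submitters' processing notes the arrays were scaled to a common target, and the mean after trimming 2% at each end was 500.2 in every array, so no further scaling was applied. The table held 22283 probe sets, of which 68 controls were left out.

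Signals were taken as log2 after adding 12.49, the 10th percentile of all values. A probe set was kept if its mean in at least 1 of the 27 groups reached the median of all log2 values, 7.24, which is a signal of 138.9. This kept 13422 of 22215 probe sets. The platform table gave 1 gene symbol for 19065 probe sets, several for 1043 and none for 2107. Of the kept probe sets 11913 had 1 symbol, and 8105 genes had a probe set of their own. Gene counts use these genes, and each gene is described by 1 probe set. Probe sets of 1 gene were called in opposite directions for 5 genes with TNF at 100 ng/ml against untreated cells.

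All 54 arrays were fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 27 groups and 27 residual degrees of freedom. Variances were moderated with an intensity trend, and the median prior degrees of freedom were 6.45. Each comparison was tested by the moderated F test over its contrasts at 4, 8 and 16 h, and the direction is that of their mean. Comparisons over time used both contrasts against 4 h and the direction of 16 h minus 4 h. P values were adjusted by Benjamini and Hochberg over the kept probe sets, at a level of 0.05. Replicate numbers were not used as blocks. Numbers were taken to pair arrays only where residuals of arrays with the same number correlated above 0.1 in every pair of groups. This held within 8 h, in 36 of 36 pairs, but not within 4 h (27 of 36, median 0.2) or 16 h (31 of 36, median 0.205), nor over all times (218 of 351). The 8 h set was therefore also fitted as a block, and the replicate number, over all times or within each time, was a block in 2 alternatives.

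The 35 gene lists held 784 genes, of which 580 had a kept probe set. They were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and p was adjusted over all 455 tests. Members were also adjusted over the list alone. The genes named for a comparison are the 10 largest rises and 10 largest falls among called genes, up to 4 members of each list described and 18 genes fixed in advance, 14 of which were measured. These 14 are described where they passed, and elsewhere with examples of their values. GATA6 passed in no comparison. Groups, comparisons and their tests, lists and alternatives were chosen before the data were examined, except that the settings that concern the ACTB ratio or the 8 h arrays, the regroupings and splits with the 8 h sets, and the tests on interferon-stimulated genes in untreated cells and on interferon-beta were added afterwards. Later tests on degraded RNA and on the time course of untreated cells concern patterns already seen, and only their bounds were set before those tests were run.

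The procedure was tested on simulated data with 200 changed probe sets. For TNF at 100 ng/ml against untreated cells, changes at all times were recovered in 26.9%, 79.1% and 95.5% of cases at log2 0.5, 1 and 2, and 10 of 144 calls were false. Changes at 16 h alone were recovered in 2.99%, 38.8% and 80.3%, and 12% of calls were false. For the interaction of TNF with insulin, changes at all times were recovered in 5.97%, 47.8% and 78.8%, with 9.28% false calls, and changes at 8 h alone in 0%, 7.46% and 56.1%, with 6.67% false. A list of 30 genes shifted by 0.3 had a camera adjusted p of 1.58e-18, and 1 of the 34 lists without a shift was called. Without any change 0 probe sets were called in every comparison. The simulated noise was independent between probe sets and between arrays. Real residuals of arrays with the same replicate number correlated by 0.286 to 0.576 within 8 h, so these values do not cover noise that arrays or genes share.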

Results

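HT-29 colon adenocarcinoma cells, an epithelial line, were primed for 24 h with 200 U/ml interferon-gamma and then left untreated or given tumour necrosis factor (TNF), epidermal growth factor (EGF), insulin or a mixture. The 9 treatments were no further factor, TNF at 5 or 100 ng/ml, EGF at 100 ng/ml, insulin at 500 ng/ml, TNF at 100 ng/ml with EGF at 100 ng/ml or with insulin at 500 ng/ml, and TNF at 5 ng/ml with EGF at 1 ng/ml or with insulin at 5 ng/ml. RNA was measured at 4, 8 and 16 h on Affymetrix human genome arrays, with 2 biological replicates per group, which made 54 arrays in 27 groups. Their number limits the precision of every value below. The median signal of an array lay between 110.9 and 168, and the correlation of log2 signal between the replicates of a group, taken across probe sets, lay between 0.929 and 0.977. Of 22215 probe sets, 13422 passed the filter on low signal, and they stood for 8105 genes.

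Unless a time is named, a change is the mean of the log2 differences at 4, 8 and 16 h, ± is its standard error, and n is 6 arrays for each treatment. The p of a gene is the limma F test over the 3 times, adjusted over the 13422 probe sets. A pair means the arrays of both treatments with the same time and replicate number, although the numbers were taken to tie arrays only within 8 h. In comparisons over time the pairs share their 4 h arrays. Gene groups were fixed lists, and a member rose, fell or changed only if its own adjusted p was under 0.05.

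Some 8 h arrays of replicate 2 differed from the rest in a sign of RNA quality. The ratio of ACTB signal from the 3′ end of the transcript to that from its 5′ end, which is higher in shortened RNA, had a median log2 of 0.32 in these 9 arrays and of −0.04 in the other 45. The TNF 100 ng/ml array was highest at 1.19 and the insulin 500 ng/ml array followed at 0.98. The highest array outside this set, TNF 100 ng/ml with insulin 500 ng/ml at 16 h in replicate 1, had 0.63. The replicate 2 arrays of 16 h, at 0.02 to 0.43, overlapped the 8 h set, so only the pair with 1.19 and 0.98 stood apart by this ratio. By the same ratio for GAPDH the TNF array was highest at 0.48. The insulin array, at 0.20, lay below TNF 5 ng/ml with insulin 5 ng/ml at 16 h in replicate 2, at 0.35. All 9 arrays lay narrowly apart on the third principal component (9.36% of the variance), at 15.82 or higher against at most 15.48 elsewhere. Their 10th percentile of signal had a median of 16.73, against 11.78 in the others.

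**Figure D1:**
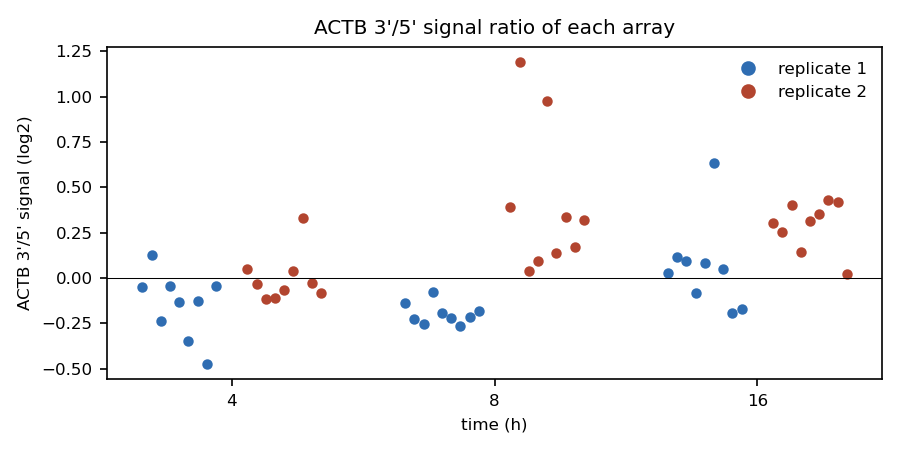
Each point is 1 of 54 arrays, with the ACTB 3′ to 5′ signal ratio (log2) on the vertical axis and the time (h) on the horizontal axis, coloured by replicate number. The replicate 2 array of TNF 100 ng/ml at 8 h lies highest at 1.19.

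The first comparison asked what TNF at 100 ng/ml did to primed cells. Most chemokine, NF-kB feedback and interferon-stimulated genes rose, and most DNA replication genes fell. The neutrophil chemoattractant CXCL8 rose most, by log2 5.00 ± 0.19 (n = 6 arrays per treatment, adjusted p = 2.12e-19), or 32.0-fold, in 6 of 6 pairs. RGS2, a regulator of G-protein signalling, fell most, by 2.66 ± 0.10 (adjusted p = 2.46e-20, 6 of 6 pairs). A total of 2194 probe sets for 1686 genes passed, 898 higher and 1296 lower, and 296 of the higher and 116 of the lower ones changed at least 2-fold.

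After CXCL8, the largest rises were those of the hexose transporter SLC2A6 at 4.63 ± 0.26, the chemokine CCL20 at 4.41 ± 0.23, the elastase inhibitor PI3 at 3.99 ± 0.16 and the chemokine CCL22 at 3.79 ± 0.25. CXCL9, which attracts T cells, rose by 3.71 ± 0.08, the cell cycle regulator RGCC by 3.68 ± 0.17 and TNFAIP3, the deubiquitinase that restrains NF-kB, by 3.64 ± 0.13. The membrane-bound chemokine CX3CL1 rose by 3.49 ± 0.10 and complement C3 by 3.47 ± 0.24. The difference from untreated cells was largest at 8 h for CCL20, at 6.60, and was 1.85 at 16 h, whereas that of C3 grew from 2.12 at 4 h to 4.87 at 16 h. The adjusted p of these rises lay between 8.58e-26 for CXCL9 and 1.03e-12 for C3, all in 6 of 6 pairs.

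Beside RGS2, the largest falls were those of the BMP and Wnt antagonist SOSTDC1 at −2.30 ± 0.25, the endocytic adaptor EPN3 at −2.28 ± 0.30, the growth factor FGF9 at −1.83 ± 0.20, ZNF395 at −1.80 ± 0.35 and the receptor FGFR3 at −1.77 ± 0.34. PPFIBP2 at −1.70 ± 0.34, the lipoic acid synthase LIAS at −1.63 ± 0.38, the transcription factor CEBPA at −1.60 ± 0.23 and the secreted Wnt inhibitor DKK1 at −1.59 ± 0.10 followed, all 10 in 6 of 6 pairs. LIAS had an adjusted p of 0.0108 and no longer passed without the 8 h arrays (adjusted p = 0.125), and PPFIBP2, at 0.00236, did not pass when only the 2 treatments were fitted (0.0785). RGS2 fell by 0.72 at 4 h and by 4.05 at 16 h.

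The NF-kB list had 15 of 19 measured members higher and 4 that did not pass, and adjusted over the list alone 16 were higher. TNIP1 rose by 2.22, NFKBIA, which encodes the inhibitor IkB-alpha, by 2.63 and the caspase-8 regulator CFLAR by 1.41. The camera test placed the list above other genes with an adjusted p of 1.84e-34. Of 23 chemokine and cytokine genes 17 rose and 6 did not pass, with CXCL2 at 2.60 and CXCL1 at 3.18; adjusted over the list alone 19 rose (camera adjusted p = 2.73e-34). Adhesion and matrix genes had 10 of 20 higher and 10 that did not pass, among them ICAM1 at 2.07, VCAM1 at 2.44 and the matrix protease MMP7 at 1.33 (11 higher adjusted over the list alone, camera adjusted p = 3.09e-10). The complement list had 7 of 11 higher and 4 that did not pass, with C1S at 2.97 and CFB at 1.69 (7 adjusted over the list alone, camera adjusted p = 2.1e-13).

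Interferon-related groups were higher although every culture had received interferon-gamma. Of 32 type I interferon-stimulated genes 29 rose and 3 did not pass, with a median of 1.07, and adjusted over the list alone 31 rose (camera adjusted p = 1.56e-40). The antiviral gene RSAD2 rose by 2.41, the DNA sensor IFI16 by 1.95, ISG20 by 1.75 and OASL by 1.64. The median of the list was 0.31 at 4 h, 0.69 at 8 h and 2.04 at 16 h. Interferon-gamma targets had 17 of 26 higher and 9 that did not pass, with the tryptophan-degrading enzyme IDO1 at 1.68 (20 adjusted over the list alone, camera adjusted p = 5.44e-27). CXCL10 rose by 1.67 ± 0.15 (adjusted p = 9.5e-10), whereas IRF1 did not pass at 0.29 (adjusted p = 0.0996). MHC class II genes had 7 of 12 higher and 5 that did not pass, with the protease CTSS at 1.08, HLA-DRA at 0.78 and the class II transactivator CIITA at 0.55 (9 adjusted over the list alone, camera adjusted p = 9.91e-07). MHC class I genes had 4 of 16 higher, TAP1 at 0.51 among them, and 4 adjusted over the list alone (camera adjusted p = 0.0139, and adjusted p = 0.324 with an estimated correlation). The class I call was also lost after quantile normalization (adjusted p = 0.121).

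Cell cycle groups were lower. Of 28 G1/S and DNA replication genes 25 fell and 3 did not pass, with a median of −0.78 (25 adjusted over the list alone, camera adjusted p = 1.12e-18). The helicase subunits MCM6 and MCM2 fell by 1.03 and 0.89 and the ribonucleotide reductase subunit RRM2 by 0.88. Of 33 G2/M genes 13 fell and 20 did not pass, with PRC1 at −0.42 and FOXM1 at −0.63 (18 adjusted over the list alone, camera adjusted p = 0.000542). The cyclin-dependent kinase inhibitor CDKN1A rose by 2.23 and GADD45A fell by 1.50.

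In the apoptosis list 11 of 26 members rose, 2 fell and 13 did not pass; RIPK2 rose by 1.87 and the TRAIL receptor TNFRSF10B by 1.08, while the adaptor FADD fell by 0.65 (11 higher and 3 lower adjusted over the list alone, camera adjusted p = 7.41e-06). Both interferon-gamma receptor chains rose, IFNGR2 by 2.15 and IFNGR1 by 1.39, and the EGF receptor gene EGFR rose by 1.02 ± 0.15 (adjusted p = 5.08e-05, 6 of 6 pairs). ERK-responsive genes had 11 of 27 higher, 2 lower and 14 that did not pass, with the phosphatase DUSP5 at 1.77 and FOSL1 at 1.19 (11 higher and 4 lower adjusted over the list alone). The camera call of this list (adjusted p = 0.000115) was lost with an estimated correlation (adjusted p = 0.0729 with an estimated correlation). The ERK phosphatase gene DUSP6 rose by 0.82 ± 0.19 (adjusted p = 0.000178), by 1.99 at 4 h and by 0.15 at 16 h. HMGCS1 of the sterol pathway rose by 0.59 ± 0.18 (adjusted p = 0.0458) and was lost without any of 8 of the 12 arrays, up to 0.243 without TNF 16 h replicate 2. EGR1 at 0.07, EREG at 0.38, PHLDA1 at 0.24, IRS2 at 0.12, TNFRSF1A at 0.28 and GATA6 at −0.09 did not pass, with adjusted p between 0.295 and 0.908.

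By single time, 587 probe sets passed at 4 h, 755 at 8 h and 1652 at 16 h. The share of higher calls was 40.9% with the deposited scaling, 49.0% after quantile normalization (962 higher and 1003 lower) and 56.6% after median centring (1050 higher and 805 lower). Fitting only the 2 treatments gave 1160 calls. The count at 4 h fell to 306 and 390 without TNF replicate 1 or 2 and 349 without untreated replicate 2, that at 8 h to 434 and 412 without untreated replicate 1 or 2 and 448 without TNF replicate 2, and that at 16 h to 958 without untreated replicate 1 and 1051 and 1081 without TNF replicate 1 or 2.

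**Figure D2:**
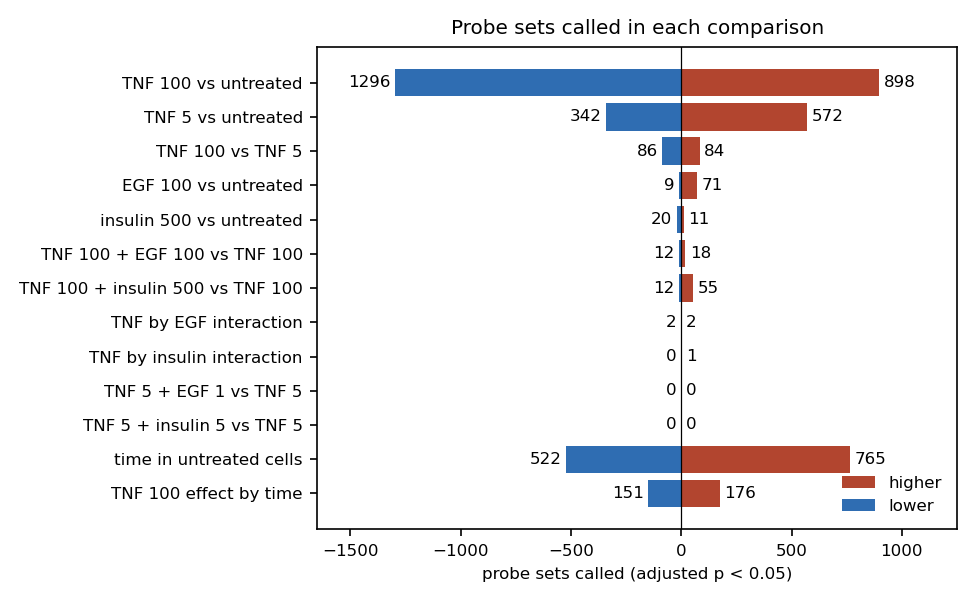
Bars give the number of probe sets called at an adjusted p under 0.05 in each of 13 comparisons, with higher ones to the right and lower ones to the left of 0. TNF at 100 ng/ml against untreated cells had 898 higher and 1296 lower calls, and the pair of low-dose mixtures had 0.

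The comparison of TNF at 5 ng/ml with untreated cells asked what a 20-fold lower concentration did. Most chemokine and NF-kB genes rose and most replication genes fell. CXCL8 rose by 4.18 ± 0.19 (n = 6 arrays per treatment, adjusted p = 7.74e-17) and CCL20 by 3.47 ± 0.23 (adjusted p = 1.52e-13), both in 6 of 6 pairs. A total of 914 probe sets for 708 genes passed, 572 higher and 342 lower, of which 172 and 17 changed at least 2-fold.

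SLC2A6 rose by 3.42 ± 0.26, the cytokine IL32 by 3.16 ± 0.16, CXCL9 by 3.13 ± 0.08, C3 by 3.02 ± 0.24, RGCC by 2.79 ± 0.17, TNFAIP3 by 2.71 ± 0.13, CCL22 by 2.62 ± 0.25 and the chemokine CXCL1 by 2.46 ± 0.14, each in 6 of 6 pairs and with an adjusted p of at most 7.5e-09. The falls were smaller. EPN3 fell by 1.70 ± 0.30 (adjusted p = 0.000421) and RGS2 by 1.57 ± 0.10 (adjusted p = 4.33e-15, 5 of 6 pairs), with 0.03 at 4 h and −2.88 at 16 h. FGF9 fell by 1.23 ± 0.20 (adjusted p = 0.000238), the microvillus protein gene VIL1 by 1.10 ± 0.18 (0.000154) and the transcription factor ISL1 by 1.03 ± 0.17 (0.000203).

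The calls of the other large falls were lost when single arrays were left out. The actin nucleator COBL at −1.32 (adjusted p = 0.00575) did not pass without untreated 16 h replicate 2 (0.0605). SOSTDC1 at −1.09 (adjusted p = 0.0118) did not pass without replicate 2 at 8 h of untreated cells (0.105) or of TNF at 5 ng/ml. PPFIBP2 at −1.31, CDK5RAP2 at −1.14 and NRGN at −1.01 had adjusted p of 0.0285, 0.0312 and 0.0316, and leaving out 1 array ended the call for 6, 6 and 4 of the 12 arrays, with adjusted p up to 0.161 without TNF 5 ng/ml 16 h replicate 1, 0.162 without untreated 16 h replicate 1 and 0.245 without the same array.

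Of the NF-kB list 14 of 19 members rose and 5 did not pass, with NFKBIA at 1.94 and RELB at 2.02, and adjusted over the list alone 14 rose (camera adjusted p = 7.14e-33). Chemokines had 14 of 23 higher and 9 that did not pass, with CX3CL1 at 2.45 and CXCL2 at 1.97 (17 adjusted over the list alone, camera adjusted p = 2.52e-37). Type I interferon-stimulated genes had 28 of 32 higher and 4 that did not pass, RSAD2 at 1.70 and IFIT1 at 0.94 among them (29 adjusted over the list alone, camera adjusted p = 1.56e-40). Interferon-gamma targets had 16 of 26 higher and 10 that did not pass, with IDO1 at 1.57 and CFB at 1.36 (18 adjusted over the list alone, camera adjusted p = 2.07e-33). Of 12 MHC class II genes 6 rose and 6 did not pass, with CIITA at 0.80 and HLA-DQB1 at 0.80 (8 adjusted over the list alone, camera adjusted p = 1.56e-08). Of 28 G1/S genes 24 fell and 4 did not pass, with RRM2 at −0.80 and MCM6 at −0.77 (27 adjusted over the list alone, camera adjusted p = 5.4e-26).

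ERK-responsive genes had 13 of 27 higher, 1 lower and 13 that did not pass, with the early response gene IER3 at 0.99, DUSP5 at 1.34 and FOSL1 at 0.84 (16 higher and 2 lower adjusted over the list alone, camera adjusted p = 7.5e-09). PHLDA1 rose by 0.53 ± 0.13 (adjusted p = 0.00325) and DUSP6 by 0.64 ± 0.19 (0.000368), the latter with 2.01 at 4 h and −0.13 at 16 h. EGR1 rose by 0.59 ± 0.17 (adjusted p = 0.0028), with 1.58 at 4 h, and did not pass without untreated 4 h replicate 1 (0.0773). EREG, which encodes an EGF receptor ligand, had an adjusted p of 0.0431 at 0.61, and leaving out any of 8 of the 12 arrays ended the call, up to 0.322 without TNF 5 ng/ml 4 h replicate 2. CXCL10 rose by 1.48 ± 0.15 (adjusted p = 3.05e-08), and EGFR did not pass at 0.50 (adjusted p = 0.176). The ATF4 and amino acid response list had 8 of 25 higher, 1 lower and 16 that did not pass, with VEGFA at 1.13 and the cystine transporter SLC7A11 at 0.59 (10 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.000257, and adjusted p = 0.171 with an estimated correlation).

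By single time 252 probe sets passed at 4 h, 390 at 8 h and 654 at 16 h. Fitting only the 2 treatments gave 490 calls, and the counts at single times fell to 139 or fewer at 4 h without either TNF 5 ng/ml array, to 255 and 167 at 8 h without untreated replicate 1 or 2 and 248 without TNF replicate 1, and to 344 at 16 h without untreated replicate 1 and 348 without TNF replicate 2.

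The direct comparison of both TNF concentrations asked which changes grew with the dose. PI3 rose by a further 1.72 ± 0.16 (n = 6 arrays per treatment, adjusted p = 9.89e-08) and the chemokine CCL5 by 1.62 ± 0.18 (adjusted p = 4.06e-07). DKK1 was lower by 1.02 ± 0.10 (adjusted p = 3.62e-08) and RGS2 by 1.09 ± 0.10 (adjusted p = 9.03e-08), all in 6 of 6 pairs. A total of 170 probe sets for 143 genes passed, 84 higher and 86 lower. With the 8 h replicate set as a block the count was 286.

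Among other genes that were higher, the secreted protein MIA rose by 1.51 ± 0.26 (adjusted p = 0.00314), CX3CL1 by 1.05 ± 0.10 (3.62e-08), the protease inhibitor WFDC2 by 0.95 ± 0.12 (2.75e-05), TNFAIP3 by 0.93 ± 0.13 (0.000533) and NFKBIA by 0.69 ± 0.11 (0.00137). CCL5 stood 0.97 higher at 4 h and 2.77 higher at 16 h. The type I interferon gene IFNB1 was higher by 1.24 ± 0.26 (adjusted p = 0.00133), by 0.39 at 4 h and 2.90 at 16 h. Its call was lost without TNF 5 ng/ml 16 h replicate 2 (0.103), without a pseudocount (0.136) and when only both treatments were fitted (0.202). Among the lower ones, the BMP target ID1 fell by 0.95 ± 0.10 (9.03e-08), the stress cytokine GDF15 by 0.81 ± 0.13 (0.000929) and the TGF-beta receptor TGFBR2 by 0.72 ± 0.10 (3.62e-05). ID1 was 1.81 lower at 4 h and 0.43 lower at 16 h.

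Several calls here were lost when single arrays were left out. CXCL8 at 0.82 (adjusted p = 0.0172) was lost without TNF 100 ng/ml 16 h replicate 2 (0.215) or either 16 h array of TNF at 5 ng/ml. FOS at −1.16 (0.0172), the glutathione-degrading enzyme CHAC1 at −0.92 (0.00294) and the zinc exporter SLC30A1 at −0.75 (0.0139) were lost without TNF 100 ng/ml 4 h replicate 1, with adjusted p of 0.304, 0.127 and 0.351. SLC24A1 at 1.33, SLC2A6 at 1.21 and CCL22 at 1.16 were lost without any of 11, 11 and 10 of the 12 arrays, and CEBPA at −1.14 without any of 9. TRAF1 at 1.05 and SOSTDC1 at −1.20 were each lost without any of 4.

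In the NF-kB list 7 of 19 members were higher and 12 did not pass, with RELA at 0.53 and CFLAR at 0.66 (8 adjusted over the list alone, camera adjusted p = 3.64e-23). Chemokines had 7 of 23 higher and 16 that did not pass, with the death ligand TNFSF10 at 0.53 and CXCL2 at 0.63 (11 adjusted over the list alone, camera adjusted p = 7.72e-20). Of 32 type I interferon-stimulated genes only ISG20 at 0.66 and OASL at 0.61 passed, 30 did not, and the list median was 0.26 (4 adjusted over the list alone, camera adjusted p = 8.43e-18). The ATF4 list had 3 of 25 lower and 22 that did not pass, with the mTOR inhibitor DDIT4 at −0.64 and TRIB3 at −0.29 (7 adjusted over the list alone, camera adjusted p = 0.00135, and adjusted p = 0.242 with an estimated correlation). This list call was also lost without TNF 5 ng/ml 8 h replicate 1 (0.125). Of the members named, DDIT4 was lost without either 4 h array of replicate 1 (up to 0.151), TRIB3 without any of 11 of the 12 arrays (up to 0.22) and TNFSF10 without TNF 100 ng/ml 8 h replicate 2 (0.0507). G1/S genes had 0 of 28 that passed, RFC4 at −0.33 being the nearest, and 1 lower adjusted over the list alone (camera adjusted p = 0.0126, and adjusted p = 0.108 with an estimated correlation).

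The share of higher calls was 49.4% with the deposited scaling, 62.0% after quantile normalization (103 higher and 63 lower) and 68.6% after median centring (127 higher and 58 lower). The count fell to 104 without TNF 5 ng/ml 16 h replicate 2, 106 without TNF 100 ng/ml 4 h replicate 1, 108 and 110 without replicate 1 or 2 of TNF 5 ng/ml at 4 h, 111 without TNF 100 ng/ml 16 h replicate 2 and 49 when only both treatments were fitted.

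The comparison of EGF at 100 ng/ml with untreated cells asked what the survival factor did alone. Of 27 ERK-responsive genes 8 rose. DKK1 rose by 1.17 ± 0.10 (n = 6 arrays per treatment, adjusted p = 3.68e-09) in 6 of 6 pairs, and CAPRIN2, an RNA-binding protein gene, by 1.35 ± 0.14 (adjusted p = 1.42e-06), also in 6 of 6. A total of 80 probe sets for 63 genes passed, 71 higher and 9 lower. With the 8 h replicate set as a block the count was 131.

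The small GTPase gene ARL14 rose by 1.20 ± 0.15 (adjusted p = 3.18e-05), CDKN1A by 1.15 ± 0.19 (2.44e-05), the complement inhibitor CD55 by 1.01 ± 0.11 (2e-07), FOSL1 by 0.98 ± 0.11 (1.42e-06), ID1 by 0.97 ± 0.10 (7.15e-09) and PHLDA1 by 0.95 ± 0.13 (7e-06). HBEGF, which encodes a ligand of the EGF receptor, rose by 1.12 ± 0.24 (0.000194), with 3.07 at 4 h and −0.20 at 16 h. The difference from untreated cells shrank from 2.58 at 4 h to 0.09 at 16 h for CDKN1A and from 2.07 to −0.04 for ID1, a gene that, like HBEGF and EGR1, rose over these times in untreated cells. EGR1 rose by 0.67 ± 0.17 (0.00149), by 1.96 at 4 h and 0.03 at 16 h, and did not pass without 4 h replicate 1 of untreated cells (0.0795) or of EGF. The neurotensin receptor NTSR1 at 1.35 had an adjusted p of 0.0352 and was lost without any of 8 of the 12 arrays, up to 0.52 without untreated 8 h replicate 2.

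The selenium-binding protein gene SELENBP1 fell by 0.73 ± 0.10 (adjusted p = 0.000307, 6 of 6 pairs). The mTOR inhibitor DEPTOR at −0.65, HCP5 at −0.60 and PRR15L at −0.53 had adjusted p of 0.0355, 0.0195 and 0.0201 and were lost without any of 9, 5 and 4 arrays. RGS2 passed (adjusted p = 0.0275) with a mean change of −0.00, because it was 0.74 at 4 h and −0.55 at 16 h, and was lost without any of several arrays, up to 0.218 without untreated 4 h replicate 1. CXCL8 at 0.86 (adjusted p = 0.0628), EGFR at 0.67 (0.114), NFKBIA at −0.01, TNFAIP3 at 0.10 and GATA6 at −0.18 did not pass.

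ERK-responsive genes had 8 of 27 higher and 19 that did not pass, with FOSL1, PHLDA1 and EGR1 above and IER3 at 0.33 (16 adjusted over the list alone, camera adjusted p = 2.02e-21). The median of the list was 0.78 at 4 h, 0.29 at 8 h and 0.12 at 16 h. In untreated cells the list itself rose between 4 and 16 h, by a median of 1.44 with 18 of 27 members higher. The smaller difference at 16 h therefore does not show that these genes fell in cells given EGF. Apoptosis genes had 2 of 26 higher, TNFRSF10B at 0.52 and the survival gene MCL1 at 0.39, and 24 that did not pass (3 adjusted over the list alone, camera adjusted p = 0.00205). Both calls were lost without any of several arrays, 4 for TNFRSF10B and 9 for MCL1, up to 0.105 and 0.474 without EGF 4 h replicate 2. Ribosome biogenesis genes had 0 of 23 that passed, MYC at 0.38 and NOLC1 at 0.27 among them, and 1 higher adjusted over the list alone (camera adjusted p = 0.00106). Fitting only both treatments gave 13 calls, which did not include CDKN1A (0.146), SELENBP1 (0.0836) or EGR1 (0.0836).

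The comparison of insulin at 500 ng/ml with untreated cells asked the same of the other survival factor. DEPP1, a FOXO target, fell most, by 1.44 ± 0.18 (n = 6 arrays per treatment, adjusted p = 2.68e-06) in 6 of 6 pairs, and by 2.96 at 4 h. FOSL1 rose by 0.82 ± 0.11 (adjusted p = 0.000449), also in 6 of 6. A total of 31 probe sets for 30 genes passed, 11 higher and 20 lower. With the 8 h replicate set as a block the count was 87.

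The zinc-binding protein gene YPEL5 fell by 0.79 ± 0.10 (adjusted p = 9.53e-05), the arginine-synthesis enzyme ASS1 by 0.81 ± 0.11 (0.000449) and the transcription factor HBP1 by 0.58 ± 0.10 (1.14e-05), the last by 1.65 at 4 h. These 5 genes passed without any single array. The following calls were each ended by the loss of at least 1 array. Higher were CDKN1A at 0.80, DDIT4 at 0.58, WDR3 at 0.55, ID1 at 0.52, PHLDA1 at 0.48, IER3 at 0.45, CDC42EP2 at 0.43 and SLC7A11 at 0.26, with adjusted p from 0.00798 for ID1 to 0.0331 for DDIT4. Their adjusted p reached 0.108 for ID1 and 0.117 for IER3 without insulin 4 h replicate 2, 0.246 for CDKN1A and 0.318 for CDC42EP2 without untreated 4 h replicate 1, 0.309 for DDIT4 without untreated 4 h replicate 2, 0.383 for PHLDA1 without insulin 4 h replicate 1, and 0.207 for WDR3 and 0.238 for SLC7A11 without insulin 8 h replicate 2. Lower were the steroid enzyme HSD17B2 at −0.73, the autophagy receptor NBR1 at −0.65, SELENBP1 at −0.58, KLHDC2 at −0.55, HLA-DPB1 at −0.52 and CYP1B1 at −0.46, with adjusted p from 0.0108 for HSD17B2 to 0.0353 for CYP1B1. These reached 0.0961 without insulin 16 h replicate 1, 0.107 without insulin 4 h replicate 1, 0.0784 without untreated 8 h replicate 2, 0.073 without insulin 4 h replicate 2, 0.122 without insulin 8 h replicate 2 and 0.203 without insulin 4 h replicate 1, in that order.

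MHC class II genes had 1 of 12 lower, HLA-DPB1, and 11 that did not pass, with CIITA at −0.63 and HLA-DRB4 at −0.58; adjusted over the list alone 7 were lower (camera adjusted p = 5.44e-12). Ribosome biogenesis genes had 0 of 23 that passed, BYSL at 0.51 and NOP16 at 0.46 among them, and 2 higher adjusted over the list alone (camera adjusted p = 1.52e-06). FOXO targets had 0 of 13 that passed, with ERBB3 at −0.54 and BCL6 at −0.45, and 4 lower adjusted over the list alone (camera adjusted p = 0.00287). Sterol genes had 0 of 18 that passed, with HMGCS1 at 0.62 and LSS at 0.42, and 0 adjusted over the list alone (camera adjusted p = 0.00102, and adjusted p = 0.0541 with an estimated correlation). G1/S genes had 0 of 28 that passed, with MCM6 at 0.23, and 0 adjusted over the list alone (camera adjusted p = 0.0011). The insulin receptor substrate gene IRS2 at −0.65 (adjusted p = 0.534) and NFKBIA at −0.25 (0.061) did not pass.

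The insulin 8 h array of replicate 2 had the ACTB ratio of 0.98 given above. Leaving out 1 array gave between 11 and 54 calls, with 11 and 14 without insulin 4 h replicate 2 or 1, 18 and 19 without untreated replicate 2 at 4 h or 8 h and 54 without insulin 8 h replicate 1, and fitting only both treatments gave 0 calls.

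The addition of EGF to TNF, both at 100 ng/ml, asked what EGF did in the presence of TNF. DKK1 was higher than with TNF alone by 1.73 ± 0.10 (n = 6 arrays per treatment, adjusted p = 9.58e-14), in 6 of 6 pairs, and by 2.40 at 8 h. PHLDA1 was higher by 0.98 ± 0.13 (adjusted p = 0.000199) and RGS2 by 0.75 ± 0.10 (0.000199), both in 6 of 6. A total of 30 probe sets for 28 genes passed, 18 higher and 12 lower.

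ID1 was higher by 0.67 ± 0.10 (adjusted p = 7.42e-05), with 1.50 at 4 h and 0.12 at 16 h. The actin regulator MTSS1 at 0.66 (adjusted p = 0.0074), KRT19, a keratin of simple epithelia, at 0.57 (0.00893) and the stress gene NDRG1 at 0.68 (0.0125) were lost without TNF 16 h replicate 2 (0.0552, 0.0653 and 0.14). CHAC1 at 0.91 (0.0074) and DDIT4 at 0.57 (0.00861) were higher, and ASNS at −0.55 (0.000943), PCK2 at −0.51 (0.0074) and PHGDH at −0.68 (0.0204) were lower. All 5 are in the ATF4 list, of which 2 members of 25 rose, 3 fell and 20 did not pass (2 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.262). These calls were lost without TNF 4 h replicate 1, at adjusted p of 0.25 for CHAC1, 0.371 for DDIT4, 0.0503 for ASNS and 0.165 for PHGDH, and PCK2 was lost without TNF with EGF 4 h replicate 1 (0.117). SPRR1B at 0.91, the phospholipase PLA1A at −1.05, WFDC2 at −0.63, the iron-sequestering LCN2 at −0.56, SELENBP1 at −0.53 and UBE4B at −0.24 had adjusted p between 0.0217 and 0.0477 and were lost without any of 6 to 11 of the 12 arrays. CXCL8 at −0.08, CXCL10 at 0.01, NFKBIA at −0.15 and TNFAIP3 at −0.20 did not pass.

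MHC class II genes had 0 of 12 that passed, HLA-DPB1 at −0.37 and CIITA at −0.41 among them, and 1 lower adjusted over the list alone (camera adjusted p = 6.32e-05). ERK-responsive genes had 1 of 27 higher, PHLDA1, and 26 that did not pass (1 adjusted over the list alone, camera adjusted p = 6.54e-05, and adjusted p = 0.0649 with an estimated correlation). Junction and keratin genes had 1 of 21 higher, KRT19, and 20 that did not pass, with KRT8 at 0.17 (1 adjusted over the list alone, camera adjusted p = 0.000939). G1/S genes had 0 of 28 that passed, with GINS2 at −0.71 and MCM2 at −0.38, and 1 lower adjusted over the list alone (camera adjusted p = 0.000706).

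The share of higher calls was 60% with the deposited scaling and 72.7% after median centring (16 higher and 6 lower). The count fell to 7 without TNF 4 h replicate 1, 13 without TNF with EGF 4 h replicate 1, 14 without TNF 16 h replicate 2, 15 without TNF 8 h replicate 2, 18 without TNF with EGF 8 h replicate 2 and 19 without TNF with EGF 16 h replicate 1, rose to 47 (33 higher and 14 lower) without TNF 8 h replicate 1 and 51 (16 higher and 35 lower) without TNF with EGF 8 h replicate 1, and was 2 when only both treatments were fitted.

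The addition of insulin at 500 ng/ml to TNF at 100 ng/ml asked what insulin did in the presence of TNF. Of 25 amino acid response genes 10 were higher than with TNF alone, with the highest list median at 8 h. DDIT4 was higher by 1.27 ± 0.14 (n = 6 arrays per treatment, adjusted p = 9.64e-07) and CHAC1 by 1.45 ± 0.20 (adjusted p = 4.04e-05), both in 6 of 6 pairs and both most at 4 h, with 2.10 and 2.67. A total of 67 probe sets for 60 genes passed, 55 higher and 12 lower, and 8, 50 and 22 passed at 4, 8 and 16 h. Leaving out 1 array gave between 3 and 21, 17 and 154, and 0 and 30 calls at these times. With the 8 h replicate set as a block the count was 164.

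The glucocorticoid-induced gene TSC22D3 was higher by 0.89 ± 0.11 (adjusted p = 2e-05), PHLDA1 by 0.88 ± 0.13 (8.31e-05), DKK1 by 0.86 ± 0.10 (1.26e-05), GDF15 by 0.80 ± 0.13 (0.000339) and ID1 by 0.76 ± 0.10 (3.11e-05). TSC22D3 was 1.58 higher at 8 h and 0.36 at 16 h, and with the mean of all its probe sets it did not pass (0.718). Without the 8 h arrays TSC22D3 (0.196), PHLDA1 (0.225) and GDF15 (0.347) did not pass. GADD45A at 0.77 (0.0153) was lost without TNF with insulin 8 h replicate 1 (0.339) or either 8 h array of TNF alone (0.0913 and 0.112), and the polyamine oxidase SMOX at 0.75 (0.016) without TNF 8 h replicate 2 (0.354) or TNF with insulin 8 h replicate 1 (0.343). HBEGF at 0.92 (0.0459) was lost without any of 10 of the 12 arrays.

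HBP1 was lower by 0.61 ± 0.10 (adjusted p = 0.000284), and YPEL5 by 0.28 ± 0.10 (0.00108), with −0.91 at 4 h and 0.59 at 16 h. The nucleotide hydrolase NUDT1 at −0.88 (0.00281) was lost without TNF 16 h replicate 2 (0.143), NLE1 at −0.31 (0.0112) without the same array (0.436), ARHGDIB at −0.81 (0.0171) without TNF with insulin 16 h replicate 2 (0.181), and KLF11 at −0.58 (0.00357) and the urokinase receptor PLAUR at −0.17 (0.00202) without TNF 4 h replicate 1 (0.125 and 0.0549). GABRP at −0.61 and HECA at −0.19 had adjusted p of 0.0309 and 0.0465 and were lost without any of 6 and 9 arrays. CXCL8 at −0.22, NFKBIA at −0.09, TNFAIP3 at −0.02, GATA6 at −0.26 and IRS2 at −0.48 did not pass.

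The ATF4 and amino acid response list had 10 of 25 members higher and 15 that did not pass, with SLC7A11 at 0.70 and its partner SLC3A2 at 0.64, and adjusted over the list alone 20 were higher and 1 lower (camera adjusted p = 3.52e-24). Its median was 0.11 at 4 h, 0.91 at 8 h and 0.12 at 16 h. The TNF 8 h array of replicate 2 was the one with the highest ACTB ratio, 1.19. ERK-responsive genes had 4 of 27 higher, 1 lower and 22 that did not pass, with DUSP1 at 0.35 and FOSL1 at 0.34 (13 higher and 2 lower adjusted over the list alone, camera adjusted p = 3.53e-06). DUSP1 was lost without TNF 8 h replicate 2 (0.135) or TNF with insulin 8 h replicate 1, and FOSL1 without any of 5 arrays, up to 0.275 without the latter. The count over all times was 29 without TNF 16 h replicate 2, 38 without replicate 2 of TNF or replicate 1 of TNF with insulin at 8 h, 112 without TNF 8 h replicate 1, and 2 when only both treatments were fitted.

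**Figure D3:**
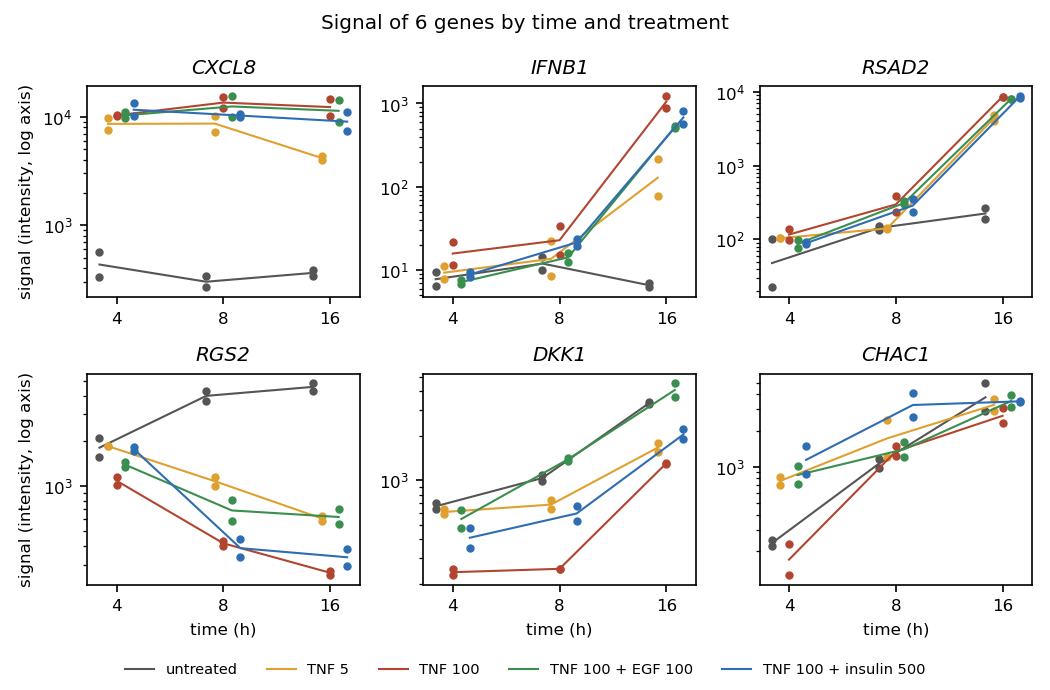
Signal (intensity, log axis) of 6 genes against time (h) in untreated cells, both TNF doses and TNF with EGF or insulin; points are single arrays and lines join the geometric means of 2 replicates. RSAD2 lay at 8648 and 8631 with TNF at 100 ng/ml at 16 h, against 189.7 and 265.9 in untreated cells.

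The interaction of TNF with EGF asked whether EGF acted differently in the presence of TNF. It is the change that EGF made on top of TNF minus the change it made alone. RGS2 was higher by 0.75 ± 0.15 (n = 6 arrays in each of 4 treatments, adjusted p = 0.000978, 4 of 6 pairs), with −0.38 at 4 h and 1.74 at 16 h. DKK1 was higher by 0.57 ± 0.14 (adjusted p = 0.00482, 4 of 6 pairs), with −0.54 at 4 h and 1.14 at 8 h, and its call was lost without the 8 h arrays (0.0958) and by the test of the mean (0.261). CX3CL1 was lower by 0.86 ± 0.14 (adjusted p = 0.0416, 6 of 6 pairs) and was lost without any of 19 of the 24 arrays, up to 0.202 without TNF with EGF 4 h replicate 1. These 4 probe sets for 3 genes were all that passed over the 3 times, 2 higher and 2 lower, whereas 358 had an unadjusted p under 0.05. By single time 2 passed at 4 h, both lower, 0 at 8 h and 1 at 16 h. CDKN1A was lower by 2.46 at 4 h (adjusted p = 0.0366 by the moderated test at that time) but did not pass over the 3 times (0.135). The calls at 4 h depended on single arrays. After quantile normalization 2 were higher and 3 lower.

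ERK-responsive genes had 0 of 27 that passed, with FOSL1 at −0.65 and EGR1 at −0.50, and 2 lower adjusted over the list alone (median −0.23, camera adjusted p = 1.56e-08). Chemokines had 1 of 23 lower, CX3CL1, and 22 that did not pass, with CXCL8 at −0.93 (1 adjusted over the list alone, camera adjusted p = 0.000935). MHC class II genes had 0 of 12 that passed, with CIITA at −0.52 and HLA-DQB1 at −0.53, and 0 adjusted over the list alone (camera adjusted p = 6.99e-05). Ribosome biogenesis genes had 0 of 23 that passed, with NOLC1 at −0.37, and 0 adjusted over the list alone (camera adjusted p = 0.000993). Type I interferon-stimulated genes had 0 of 32 that passed, with OASL at −0.37, and 0 adjusted over the list alone (camera adjusted p = 1.79e-05, and adjusted p = 0.0529 with an estimated correlation). Leaving out 1 array gave between 2 and 9 calls.

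The interaction of TNF with insulin asked the same for insulin. A single probe set passed, that of the class II gene HLA-DPB1, higher by 0.88 ± 0.13 (n = 6 arrays in each of 4 treatments, adjusted p = 0.0152) in 6 of 6 pairs. It was lost after quantile normalization (0.0594), after median centring (0.0726), when only the 4 treatments were fitted (0.159), without the 9 replicate 2 arrays of 8 h (0.222), without the 8 h time (0.251) and without any of 6 of the 24 arrays, up to 0.0674 without untreated 8 h replicate 1. An unadjusted p under 0.05 was reached by 706 probe sets. With the 8 h replicate set as a block 19 probe sets passed, and leaving out 1 array gave between 0 and 10.

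MHC class II genes had 1 of 12 higher, HLA-DPB1, and 11 that did not pass, with HLA-DRB4 at 0.95 and CIITA at 0.69; adjusted over the list alone 7 were higher (camera adjusted p = 5.04e-12). The ATF4 list had 0 of 25 that passed, with PSPH at 0.85, PHGDH at 0.72 and ASNS at 0.63, and 10 higher adjusted over the list alone (camera adjusted p = 5.62e-13). Its median was 0.35 at 4 h, 0.71 at 8 h and 0.12 at 16 h. G1/S genes had 0 of 28 that passed, with TYMS at −0.77, and 0 adjusted over the list alone (camera adjusted p = 1.23e-06). Sterol genes had 0 of 18 that passed, with HMGCS1 at −0.90 and MSMO1 at −0.77, and 0 adjusted over the list alone (camera adjusted p = 3.24e-05). Ribosome biogenesis genes had 0 of 23 that passed, with NOP14 at −0.43, and 0 adjusted over the list alone (camera adjusted p = 0.000715). Among the other genes described throughout, PHLDA1 at 0.40 (0.162), TSC22D3 at 0.69 (0.082), DUSP6 at 0.02 and GATA6 at −0.01 did not pass. On simulated data of this comparison, with noise independent between arrays, changes present at all times were recovered in 47.8% of cases at log2 1 and 78.8% at log2 2. Changes at 8 h alone were recovered in 7.46% and 56.1%.

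The low-dose mixtures asked whether EGF at 1 ng/ml or insulin at 5 ng/ml had an effect in the presence of TNF at 5 ng/ml. For EGF, limma called 0 probe sets over the 3 times and 1 at 16 h, which became 0 without either TNF with EGF array or TNF replicate 2 of that time, 560 had an unadjusted p under 0.05, and 7 of the other settings called 1. DKK1 at 0.51 ± 0.10 (adjusted p = 0.315) and PHLDA1 at 0.43 ± 0.13 (adjusted p = 1) did not pass. Leaving out 1 array gave between 0 and 5 calls. Heat shock genes had 0 of 13 that passed, with HSPA6 at 0.62, and 0 adjusted over the list alone (camera adjusted p = 0.00106), which was lost after quantile normalization (0.0675). Matrix and adhesion genes had 0 of 20 that passed, with SERPINE2 at 0.58, and 1 higher adjusted over the list alone (camera adjusted p = 6.32e-05). For insulin, limma called 0 probe sets, 279 had an unadjusted p under 0.05, and leaving out 1 array gave between 0 and 3. CXCL8 at 0.18, NFKBIA at 0.09 and IRS2 at −0.26 did not pass, and no other setting called a probe set.

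Change over time in untreated cells gave the background for the time courses, with 16 h minus 4 h as the change. Most ERK-responsive and amino acid response genes rose, and most DNA replication genes fell. HBEGF rose by 5.83 ± 0.41 (n = 2 arrays per time, adjusted p = 1.03e-11), or 56.8-fold, and GDF15 by 4.04 ± 0.23 (adjusted p = 3.62e-14), both in 4 of 4 pairs counted over 8 h and 16 h against 4 h. A total of 1287 probe sets for 1018 genes passed, 765 higher and 522 lower, with 43 between 4 and 8 h and 1372 between 4 and 16 h. The former fell to 16 without 8 h replicate 2, and the latter to 829 and 748 without 16 h replicate 1 or 2 and 886 without 4 h replicate 2.

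CHAC1 rose by 3.96 ± 0.35, DDIT4 by 3.85 ± 0.24, PHLDA1 by 3.72 ± 0.22, TSC22D3 by 3.28 ± 0.20, ID1 by 2.94 ± 0.18, KLF6 by 2.81 ± 0.44, EGR1 by 2.65 ± 0.30 and the stress gene HERPUD1 by 2.57 ± 0.20, with adjusted p of at most 3.58e-05. KLF6 did not pass when only untreated arrays were fitted (0.108). DUSP6 rose by 2.14 ± 0.32 (adjusted p = 1.51e-05) and EREG by 2.10 ± 0.32 (5.44e-05), and EGFR by 0.81 ± 0.26 (0.00116), which was lost without 16 h replicate 2 (0.0586). DEPP1 fell by 2.78 ± 0.31 (adjusted p = 1.19e-07), INSIG1, a brake on sterol synthesis, by 2.70 ± 0.36 (3.72e-07), NT5DC2 by 1.77 ± 0.26 (2.84e-05), the ribosome recycling factor ABCE1 by 1.53 ± 0.21 (1.51e-05) and the splicing factor SRSF5 by 1.47 ± 0.18 (1.75e-06). NFKBIA fell by 0.95 ± 0.19 (0.00103) and HMGCS1 by 1.61 ± 0.32 (1.05e-05). PRMT7 at −2.93 (0.00246) was lost without 16 h replicate 1 (0.0546), and HACD3 at −1.78 (0.0139), KBTBD4 at −2.55 (0.012) and ALG12 at −2.09 (0.0121) without 16 h replicate 2 (0.273, 0.119 and 0.183). NCS1 at −2.08 (0.0483) was lost without any of the 6 arrays, up to 0.318 without 16 h replicate 1.

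The ATF4 list had 21 of 25 members higher and 4 that did not pass, with a median of 1.70, ATF3 at 2.77 and TRIB3 at 2.57 (23 adjusted over the list alone, camera adjusted p = 1.2e-34). ERK-responsive genes had 18 of 27 higher and 9 that did not pass, with IER3 at 2.26 and JUNB at 2.01 (22 adjusted over the list alone, camera adjusted p = 2.83e-21). Type I interferon-stimulated genes had 17 of 32 higher and 15 that did not pass, with IRF7 at 1.47 and OASL at 1.36 (22 higher and 2 lower adjusted over the list alone, camera adjusted p = 1.59e-11). Of 12 MHC class II genes 7 rose and 5 did not pass, with HLA-DPB1 at 1.40 and HLA-DPA1 at 1.55 (8 adjusted over the list alone, camera adjusted p = 5.17e-09). Of 28 G1/S genes 20 fell and 8 did not pass, with the nuclease FEN1 at −1.54 and GINS1 at −1.82 (22 adjusted over the list alone, camera adjusted p = 7.26e-17). G2/M genes had 18 of 33 lower and 15 that did not pass, with CDC20 at −1.34 and DLGAP5 at −1.20 (26 adjusted over the list alone, camera adjusted p = 1.05e-15). Sterol genes had 6 of 18 lower, 2 higher and 10 that did not pass, with IDI1 at −1.58 (7 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.000542). The count fell to 690 and 710 without 16 h replicate 2 or 1 and to 360 when only untreated arrays were fitted.

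The last comparison asked whether the effect of TNF at 100 ng/ml differed between 16 h and 4 h. Of 32 type I interferon-stimulated genes 20 were raised more at 16 h. IFNB1 gained 5.31 ± 0.64 (n = 2 arrays per treatment and time, adjusted p = 3.32e-07, 3 of 4 pairs) and CCL5 gained 3.99 ± 0.44 (adjusted p = 3.32e-07, 4 of 4). RGS2 lost 3.32 ± 0.25 (adjusted p = 1.92e-10). A total of 327 probe sets for 274 genes passed, 176 higher and 151 lower.

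IFIT1 gained 3.77 ± 0.37 (adjusted p = 2.35e-08), IFI16 3.13 ± 0.33 (2.75e-07), the adhesion molecule VCAM1 3.60 ± 0.56 (0.00024), the lymphotoxin gene LTB 3.13 ± 0.54 (0.00131) and IDO1 2.65 ± 0.29 (8.29e-07). BMP4 gained 4.99 ± 0.81 (0.000559) and did not pass when only both treatments were fitted (0.0675). REL, an NF-kB subunit, lost 3.01 ± 0.49 (0.00024), the ephrin EFNA1 2.40 ± 0.43 (0.00184), ST3GAL1 2.25 ± 0.42 (0.00285), CD55 2.14 ± 0.27 (4.96e-06) and CEBPD 2.10 ± 0.35 (0.00059). BHLHE41 at −2.08 (0.00859) was lost without untreated 4 h replicate 1 (0.143) or TNF 4 h replicate 2. HBEGF at −2.56 (0.0258), ANXA13 at −2.56 (0.0195), DUSP6 at −1.84 (0.0229), RAB8B at 2.15 (0.0459) and SIPA1 at 1.72 (0.0375) were lost without any of 7, 4, 6, 11 and 9 of the 12 arrays.

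Type I interferon-stimulated genes had 20 of 32 with a larger effect at 16 h and 12 that did not pass, with RSAD2 at 4.16 and MX2 at 2.65 and a median of 1.65 (28 adjusted over the list alone, camera adjusted p = 1.93e-49). Interferon-gamma targets had 7 of 26 higher and 19 that did not pass, with CXCL9 at 1.95 and SERPING1 at 1.66 (11 adjusted over the list alone, camera adjusted p = 1.73e-12). Complement genes had 4 of 11 higher and 7 that did not pass, with C1S at 2.38 and CFB at 2.03 (4 adjusted over the list alone, camera adjusted p = 1.79e-05). G1/S genes had 11 of 28 lower and 17 that did not pass, with RRM2 at −1.97 and GINS2 at −2.75 (17 lower and 1 higher adjusted over the list alone, camera adjusted p = 3.74e-16). In the chemokine list 3 of 23 rose, 4 fell and 16 did not pass, with CCL20 at −2.93 and TNFSF10 at 1.79 (3 higher and 4 lower adjusted over the list alone); its median was −0.17 but its mean 0.16 (camera adjusted p = 0.651). CXCL8 at 0.50, TNFAIP3 at −0.10, NFKBIA at 0.94 (adjusted p = 0.0568) and CXCL10 at 0.23 did not pass. The count fell to 189 and 201 without TNF 16 h replicate 1 or 2, to 192 and 209 without untreated 16 h replicate 1 or 2, and to 103 when only both treatments were fitted.

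**Figure D4:**
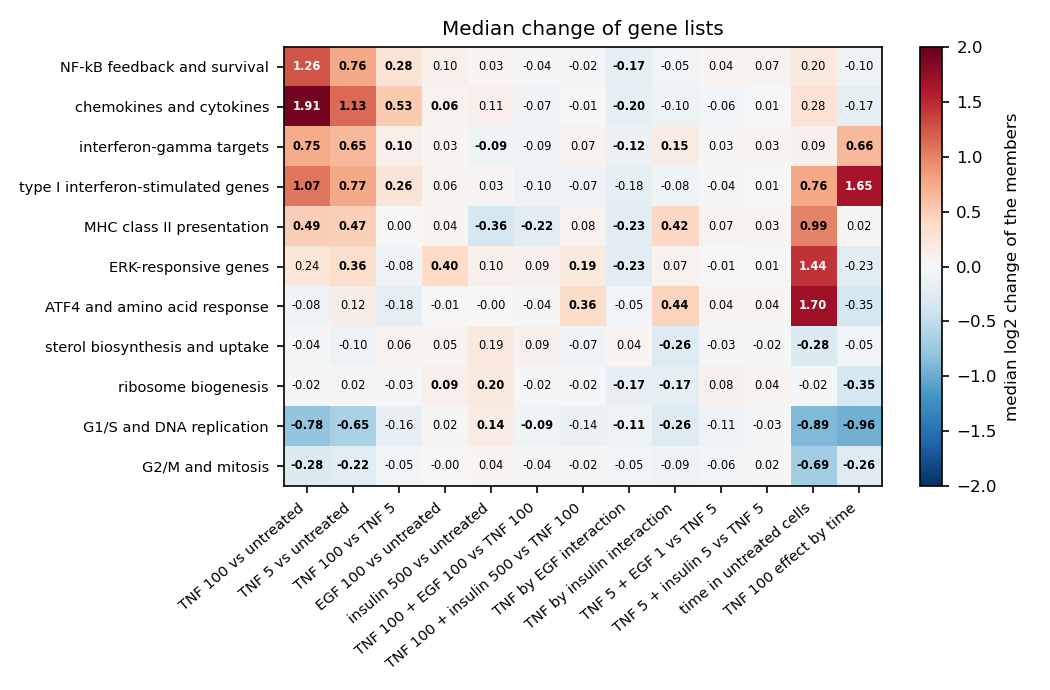
Cells give the median log2 change of the measured members of 11 gene lists (vertical axis) in 13 comparisons (horizontal axis), in bold where camera with an estimated correlation had an adjusted p under 0.05. The type I interferon-stimulated genes stood at 1.07 with TNF at 100 ng/ml and at 1.65 in its effect by time.

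Over all comparisons camera called 138 of 455 list tests with the preset correlation, and 96 of them held with an estimated correlation. Those named above without a second value held, but the very small p values rest on the preset correlation. With the estimated correlation the camera adjusted p of type I interferon-stimulated genes was 7.67e-07 in place of 1.56e-40 for TNF at 100 ng/ml. For its effect by time it was 1.49e-07 in place of 1.93e-49. For the ATF4 list it was 0.000353 in place of 3.52e-24 for insulin added to TNF, and 3.4e-05 in place of 1.2e-34 over time in untreated cells. Except for the chemokine list by time, median, mean and camera had the same direction in every list named above.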

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

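The tests on a fall of the interferon-stimulated genes in untreated cells and on interferon-beta, the regroupings and splits with the 8 h replicate sets, and the settings that concern the ACTB ratio or the 8 h arrays, were chosen only after the results were seen. The tests on degraded RNA concern patterns and arrays that had been seen first, although their bounds were set before those tests were run. The effect of TNF by time and both interactions are listed because an effect differed between times or treatments by a test of that difference, and the last paragraph weighs a pattern for which no such test was made.

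The effect of TNF at 100 ng/ml differed between times for 327 probe sets, and for the type I interferon-stimulated genes it was larger at 16 h than at 4 h by a median of 1.65, with 32 of 32 members above 0. The list did not fall in untreated cells, where its median change was 0.758 (quartiles 0.464 and 0.982, 28 of 32 members above 0), which argues against a falling baseline. With the ACTB ratio as a covariate the median of the TNF effect by time was again 1.65. At 16 h the log2 ratio was 0.11 and 0.25 with TNF and 0.03 and 0.30 in untreated cells. At 4 h it was 0.13 and −0.03 against −0.05 and 0.05. With ratios so alike the covariate could hardly change the median. The larger effect thus does not go with this ratio, but other aspects of RNA quality were not tested. A candidate explanation is interferon-beta made under TNF, since IFNB1 stood 0.49, 0.55 and 5.80 above untreated cells at 4, 8 and 16 h with 100 ng/ml and 0.11, 0.13 and 2.90 with 5 ng/ml. The list was 0.343 higher with 100 than with 5 ng/ml at 16 h (31 of 32 members above 0), 0.229 at 8 h and 0.161 at 4 h, which narrowly meets the bounds set for that explanation and leaves it a hypothesis, found and tested on the same arrays. The list already stood 0.69 and 0.53 above untreated cells at 8 h with 100 and 5 ng/ml, after 0.31 and 0.09 at 4 h. Between these times the effect of 100 ng/ml on IFNB1 changed by 0.06 ± 0.64. This is too imprecise to tell whether interferon-beta was the source of the earlier rise.

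The interaction of TNF with EGF was called for 4 probe sets. Of 100 regroupings of the residuals, with the real grouping counted among them here and below, 3 gave as many, the highest other 33. This is under the level of 5 in 100 set for this test. Under a block for the 8 h replicate set 4 were called, and 4 of 100 regroupings within the 8 h sets gave as many, the highest 92, narrowly under the same level. Because the regroupings treat the residuals of the arrays as interchangeable and single ones gave many more calls, they do not exclude chance. RGS2 differed by 0.75, DKK1 by 0.57 and CX3CL1 by −0.86 between EGF on top of TNF and EGF alone.

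The interaction of TNF with insulin was called for 1 probe set, that of HLA-DPB1 at 0.88, and 27 of 100 regroupings gave as many, the highest 2032, which points to a structure of the samples that these regroupings ignore. A block for the 8 h replicate set gave 19 calls, and 5 of 100 regroupings within the 8 h sets gave as many, the highest 277, so chance cannot be excluded with or without the block. With the replicate number within each time as a block the count was 91. Without the pair of 8 h arrays with the highest ACTB ratio the blocked count was 39, and without the replicate 2 arrays of the other 2 treatments at 8 h it was 8. Degraded RNA in that pair and other sources of the added calls therefore cannot be told apart, because leaving out either pair of arrays removed calls, and no biological explanation was tested.

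Between TNF with insulin and TNF alone 8, 50 and 22 probe sets were called at 4, 8 and 16 h, a difference between times that was not tested, and the TNF array of replicate 2 at 8 h had the highest ACTB ratio. The 50 probe sets called at 8 h changed by a median of 1.24 in the replicate 1 arrays and 1.18 in the replicate 2 arrays, a ratio of 1.05, with 50 of 50 in the same direction in each, although calls made from both replicates favour such a likeness. The ATF4 and amino acid response list, whose members were fixed in advance, rose by a median of 1.07 in replicate 1 (23 of 25 members higher) and 0.64 in replicate 2 (22 of 25), a ratio of 1.65. The list argues most directly against degraded RNA in the replicate 2 array as the whole cause, since its change was not smaller in the replicate 1 arrays. The count at 8 h nevertheless depended on single arrays, with 17 and 154 calls without TNF replicate 2 or 1 and 28 without TNF with insulin replicate 1, and with the 8 h set as a block 2 of 27 splits gave as many calls over all times, 164 as labelled and 197 in the other, so chance cannot be excluded there and insulin acting on amino acid response genes remains only a hypothesis.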

How the results depend on the processing

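The settings with the ACTB ratio, the 8 h set as a block and the arrays or times left out together were chosen only after the data were seen; the others were planned. For each count that follows, the cause of the change was not tested unless it is given.

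Fitting only the groups compared used fewer arrays and left fewer residual degrees of freedom. It gave 1160 calls for TNF at 100 ng/ml, 490 for TNF at 5 ng/ml, 49 between the doses, 13 for EGF, 0 for insulin, 2 for EGF added to TNF, 2 for insulin added to TNF, 0 for the interaction with insulin, 360 over time in untreated cells and 103 for the TNF effect by time, whereas the interaction with EGF had 5 against 4. Without the 8 h time the test covered fewer contrasts and gave 52 for EGF, 8 for EGF added to TNF, 27 for insulin added to TNF and 1 for the interaction with EGF. Without the pair of arrays with the highest ACTB ratio the counts were 15 for EGF added to TNF, 40 for insulin added to TNF, 4 for the interaction with insulin and 1 for the low-dose mixture with EGF. Without the 9 replicate 2 arrays of 8 h they were 16 for EGF added to TNF and 5 for the interaction with insulin.

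The replicate numbers did not pair the arrays over all times, since residuals of the same number correlated between −0.262 and 0.576 over all pairs of groups, but within 8 h 36 of 36 pairs correlated above 0.1, between 0.286 and 0.576, so the numbers tied the 8 h arrays, against 27 of 36 within 4 h and 31 of 36 within 16 h. As a replicate block they gave 281 calls between the doses, 136 for EGF, 74 for insulin, 126 for insulin added to TNF, 7 and 8 for the interactions with EGF and with insulin and 1 for the low-dose mixture with EGF. As a replicate block within each time they gave 3347 and 1705 calls for TNF at 100 and 5 ng/ml, 503 between the doses, 207 for EGF, 160 for insulin, 72 and 378 for EGF and insulin added to TNF, 13 and 91 for the interactions with EGF and with insulin, 1 for the low-dose mixture with EGF, 2176 over time and 736 for the TNF effect by time. The interaction with insulin had 39 calls under that block without the pair of arrays with the highest ACTB ratio. With the 8 h replicate set alone as a block the counts were 286 between the doses, 131 for EGF, 87 for insulin, 164 for insulin added to TNF, 19 for the interaction with insulin and 1 for the low-dose mixture with EGF. These blocks moved no other count by more than 1.5-fold.

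With the ACTB ratio as a covariate the counts were 293 between the doses, 86 for insulin, 8 for the interaction with EGF and 1 for the low-dose mixture with EGF. The test of the mean gave 134 for EGF and 34 for insulin added to TNF. For the interaction with insulin, quantile normalization and median centring each gave 0, no pseudocount gave 3 and the stricter filter gave 8. The interaction with EGF had 2 with the pseudocount at the 25th percentile, and the low-dose mixture with EGF had 1 with median centring and 1 without a pseudocount. Of all counts under these settings, 148 stayed within 1.5-fold and 59 did not.

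Each of the 54 arrays was left out in turn, and the lone array of a group is then assumed to vary like those of the other groups. The counts ranged from 1693 to 2247 for TNF at 100 ng/ml, from 689 to 940 for TNF at 5 ng/ml and from 104 to 208 between the doses. They ranged from 56 to 78 for EGF, from 11 to 54 for insulin, from 7 to 51 for EGF added to TNF and from 29 to 112 for insulin added to TNF. The interactions ranged from 2 to 9 with EGF and from 0 to 10 with insulin, the low-dose mixtures from 0 to 5 with EGF and from 0 to 3 with insulin, the change over time from 690 to 1225 and the TNF effect by time from 189 to 391. Of these counts 109 stayed within 1.5-fold and 65 did not.

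Among 409 values of named genes, 6294 comparisons with the 18 other settings kept direction and side of the threshold, 331 lost the call, 100 gained it, 24 changed sign without a call and 8 changed sign with one. Leaving out arrays gave 4469, 420, 19, 54 and 6. RGS2 under EGF, whose mean was −0.00, stood at 0.0225 with median centring, 0.000543 without a pseudocount, 0.0130 with the covariate, 0.0104 without the 9 arrays and 0.0942 without the 8 h time, and between −0.0706 and 0.0706 when arrays were left out. SLC7A11 under insulin was −0.0897 and DUSP1 with insulin added to TNF −0.0250 without the 8 h time, and UBE4B with EGF added to TNF was 0.0319 by the mean of its probe sets. For 73 lists, 1082 results were kept, 5 lost, 3 gained and 3 changed sign under the other settings, and 928, 2, 2 and 4 when arrays were left out.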

Other observations

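The genes and lists of the first paragraphs were picked for description only after their values were seen, as were the splits with a block. The bounds of the tests on the time programme and on splits without a block were set before those tests were run. The test on the time programme concerns a rise of amino acid response genes that had been seen first. Genes of the intestinal lineage also responded to TNF at 100 ng/ml. The transmembrane mucin MUC1 rose by 1.64 (adjusted p = 2.88e-08) and the vitamin D receptor VDR by 1.04 (2.65e-05), whereas the transcription factors MYB and HES1 fell by 1.45 (3.11e-08) and 0.88 (1.19e-06), each in 6 of 6 pairs. Of 16 intestinal transcription factors 3 rose, 5 fell and 8 did not pass, so the list did not move as a whole (camera adjusted p = 0.476), and of 12 secretory genes 3 rose and 2 fell (0.406). Among 21 oxidative stress genes 4 rose and 4 fell, with catalase, CAT, at −0.91 (1.92e-07, 6 of 6 pairs) and AKR1B10 at −0.80 (6.25e-11, 5 of 6 pairs), and camera did not call the list (0.103). Marker lists of other cells gave 1 of 8 leukocyte genes higher, the integrin ITGAM at 1.20 (1.33e-07), 1 lower, and 0 of 6 fibroblast and endothelial genes, with camera adjusted p of 0.492 and 0.906.

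In untreated cells between 4 and 16 h, the stress and growth arrest genes TXNIP at 1.88 (adjusted p = 2.53e-06), BTG1 at 1.71 (1.01e-07) and PMAIP1 at 2.03 (7.02e-06) rose, and CXCL9 fell by 1.41 (4.29e-09) after the interferon-gamma priming. The lipogenic enzyme FASN fell by 1.90 (2.8e-05), with 2 of 12 fatty acid genes lower and no camera call (0.0644), although the list was called with the stricter filter (0.0489) and when only untreated arrays were fitted (0.0475). TGF-beta and BMP targets had 5 of 13 higher and 1 lower (camera adjusted p = 0.000777, and 0.00708 with an estimated correlation). The intestinal transcription factors had 4 of 16 higher, KLF4 at 1.47 (6.79e-07) among them, and 1 lower (camera adjusted p = 0.0246), and this list call was lost without 4 h replicate 1 (0.0516), without a filter (0.0671), with the stricter filter (0.0501) and when only untreated arrays were fitted (0.0542). The effect of TNF on absorptive enterocyte genes was lower at 16 h than at 4 h, with 2 of 17 lower, 15 that did not pass and a median of −0.50 (camera adjusted p = 0.00725).

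TNF with insulin might be further along the change over time of untreated cells than TNF alone, since amino acid response genes were among those that rose in both. Across 8080 genes outside that list, the change at 8 h correlated with the change of untreated cells between 4 and 16 h with a Spearman rho of 0.290 in the replicate 1 arrays and 0.138 in the replicate 2 arrays. For EGF added to TNF the values were 0.102 and 0.033. Genes are not independent replicates, and with 1 array of each treatment in each set these rho values do not decide, so this explanation and a direct effect of insulin cannot be told apart.

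Regrouping the arrays within times gave 27 splits for each pair of treatments, the real one included. Without a block, only 1 of the 27 splits, the real one, gave as many calls in 7 comparisons, which is the smallest number that can be reached. Their real counts and the highest of the other splits were 2194 and 1796 for TNF at 100 ng/ml, 914 and 679 for TNF at 5 ng/ml, 170 and 118 between the doses, 80 and 54 for EGF, 31 and 29 for insulin, 30 and 9 for EGF added to TNF, and 67 and 54 for insulin added to TNF. In each of these the highest other split still parted the arrays as labelled at 2 of 3 times, and with all 3 times mixed at most 6 probe sets were called. These splits ignore the 8 h replicate sets. A block for those sets gave real and highest other counts of 2656 and 2263, 1200 and 939, 286 and 117, 131 and 79, 87 and 39, and 43 and 22 in the same order for the first 6 comparisons, where again 1 of 27 splits gave as many. Their counts thus met the level of 5 in 100 with and without the block, although the margin for insulin was small without it. With 27 splits a lower share cannot be reached, and the level was not corrected for the number of comparisons. Chance is therefore made less likely for these but is not excluded. For insulin added to TNF 2 of 27 gave as many, 164 as labelled and 197 in a split that kept the labelled parting at 2 of 3 times, so that level was met only without the block. For both low-dose mixtures without a block limma called 0 probe sets, with 560 and 279 at an unadjusted p under 0.05, and the highest other split called 1. Since all 27 of 27 splits must give at least 0 calls, the splits say nothing about chance here. Under the block 3 of 27 splits gave the 1 call of the mixture with EGF, the highest other 1, so chance cannot be excluded, and the mixture with insulin again had 0.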
